A study of Oryza sativa with 52 samples.

How the data were processed

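The samples are rice leaves from 4 series of 13 time points, taken every 2 h over 24 h in the field, with 1 sample per time point. Each of the 26 arrays carried 2 samples in different dyes, in most cases neighbouring time points of a series. A pair of arrays carried samples of both series of a date (the second noon of the early planting with the first noon of the late planting). The arrays came from 8 slides scanned on 3 days: slides 1 to 3 with most June samples on day 1, slide 4 with the last 4 samples of the 17 day series on day 2, and the August slides on day 3.

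Per the file headers, the scanner files hold linear intensity values made with Agilent Feature Extraction 10.5.1.1, among them the mean spot signal, the local background and a processed signal that the software had background-subtracted and dye-normalized. The authors also deposited a value table of 125722 probes in log2 units, in which 26156 of the 151878 probes are missing. The labels name Feature Extraction and the affy package as its tools, give no version of affy and do not state the steps. The medians of its columns lie between 6.09 and 6.1, so the columns had been brought to a common scale. Each of its 52 columns followed the processed signal of its own array and dye best across probes (r at least 0.971, against at most 0.923 for any other channel). Its log base was read from the slope of that relation, higher values mean more signal, and the method of centring stays unknown.

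The mean spot signals were used for the main values. They were corrected with the local background by limma's normexp method with an offset of 50, normalized by loess within arrays and by quantiles of the average intensity between arrays, and split into log2 values per channel. A probe was tested if it was well above background in at least 13 of the 52 samples, which 95556 probes were, and 339 of these were left out for spots marked as uneven outliers. The 4854 control spots were not tested, except that spike-in spots served in 1 check. The tests thus covered 95217 probes. Probes that share at least 30 bases were joined into 62920 sequence groups, the largest with 492 probes. A count of probes is thus not a count of genes. Probes of different groups may still read the same transcript, so named probes that move together need not be separate signals. In 2436 pairs of probes with identical sequence, the median SD between the spots was 0.06 on the log2 scale, against a median residual SD of 0.23 around the fitted time course.

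Levels were compared with limma's lmFit and eBayes (with trend) on all 52 samples, with series, time point and dye as terms and the array as a random block (duplicateCorrelation on 5000 probes, correlation 0.489, 35 residual degrees of freedom, prior 3.3). Time-matched samples were thus compared in every contrast. The 5 contrasts are age in June (45 minus 17 days), age in August (87 minus 59 days), date in the early planting (87 minus 45 days), date in the late planting (59 minus 17 days) and the difference between the age contrasts. Rhythms were fitted with a 24 h cosine and sine per series and dye, again with the array as a block (correlation 0.324, 39 residual degrees of freedom), and tested with the moderated F test. A swing is the fitted peak minus trough on the log2 scale. Differences in rhythm were tested on the cosine and sine terms jointly. In all of these, p-values were adjusted over the probes tested by the method of Benjamini and Hochberg with a threshold of 0.05. Time of day was estimated from 200 probes with the smallest p among those rhythmic, with a swing of at least 1 and peaks within 2 h of each other, in the 3 other series, and paired by time point in an exact sign-flip test.

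The sample numbers within a series are its time points. The numbers were treated as pairing the samples, since they stand for the same clock hours. As a check, each sample of a series was correlated across probes with the samples of each other series. The lowest correlation at the same number was 0.8 for 17 and 45 days and 0.69 for 59 and 87 days. It was 0.42 for 45 and 87 days and 0.4 for 17 and 87 days. The own number gave the best match for 13 and 12 of 13 samples within June and within August. Between dates it did so for 10 of 13 against 59 days and 7 of 13 against 87 days.

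The rule for named items was fixed before the data were examined. It takes, for each level contrast, the 10 largest rises and falls past the threshold with the same sign in at least 11 of 13 pairs, for rhythms the 10 largest mean swings among probes rhythmic in all series, and for differences in rhythm the 10 smallest adjusted p. The rule also asked for a gene symbol or product, for 1 probe per gene and for the members of gene lists (clock, flowering, photosynthesis and others). These parts could not be applied, since the files pair no probe with a gene, so no list and no clock gene was tested. For the same reason the report prints at most 2 probes that rose and 2 that fell per comparison, the top of each ranking.

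The method was tested on simulated data with 200 changed probes among the real number of probes. Of level differences of 0.25, 0.5 and 1, it found 5 of 67, 36 of 67 and 61 of 66, with 7 false calls. Of rhythms with swings of 0.5, 1 and 2, it found 4 of 67, 33 of 67 and 59 of 66, with 5 false calls, and for the swing of 2 the median error of the peak was 0.22 h. Of rhythm differences of the same sizes it found 2, 17 and 52, with 3 false calls. A weak rhythm was thus mostly missed when few probes cycled. The simulated values held no slide or scan-day effect, so these counts of false calls do not cover such effects.

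Alternatives chosen before the data were examined were the deposited value table, the processed signals with quantile normalization, no between-array step, no filter, only probes well above background in all 52 samples, no dye term, no array block, slide as a random block or a fixed term, no second noon, only the series compared, no time-point term, a replicate block of the samples of one date and time, and 24 h and 12 h terms together. Added after seeing the data were leaving out the second scan day, leaving out each time point in turn, 1 probe per sequence group and scan day as a fixed term. Chance was weighed by 100 splits, the real one included. Work was done in R 4.3.3 with limma 3.58.1, statmod 1.5.0 and data.table (version 1.17.8), and in Python 3.11.15 with matplotlib 3.10.9, with a random seed of 1.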

Results

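The leaf transcriptome of field-grown rice (the japonica table variety Koshihikari) was measured around the clock in Takatsuki, Japan. Leaves were taken every 2 h from noon to noon, which gave 13 time points per series and 4 series in all. In late June, plants of a late planting stood 17 days and plants of an early planting 45 days after transplanting. In early August, the late planting stood at 59 days and the early planting at 87 days. Each time point of a series is 1 sample without a replicate, so no p-value below measures the spread between plants. Those of the fitted models measure the spread around a fitted time course. The 52 samples were hybridized on 26 arrays of 60-base probes, 2 samples per array in different dyes. Between 48.2% and 59.2% of probes were well above background in the 17 day samples, 56.9% and 60.5% at 45 days, 55.3% and 63.0% at 59 days, and 56.2% and 63.9% at 87 days. The median spot signal ran from 57.6 to 141.7 in June samples and from 112.9 to 258.8 in August samples, and 0 spots were saturated. The tests covered 95217 probes, which fall into 62920 groups of overlapping sequence. The number of arrays limits the precision. The files used here do not pair probes with genes, so probes are identified by name and sequence, and no gene or pathway is named.

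The first question was which transcripts cycled over a day in the field, in each series. At 17 days, 71331 probes (74.9%) followed a 24 h rhythm, and 37787 of them swung at least 2-fold between trough and peak. The count was 66695 (70.0%) at 45 days, 66038 (69.4%) at 59 days and 60238 (63.3%) at 87 days. In all 4 series 40685 probes (42.7%) were rhythmic, while 7138 (7.5%) were rhythmic in none of them. Probes called rhythmic with at least a 2-fold swing peaked most often in the early morning and in the late afternoon or early evening. At 17 days, 12.7% of them peaked between 6 and 8 h and 12.1% between 16 and 18 h, against 5.1% between 10 and 12 h. At 87 days, 12.7% peaked between 6 and 8 h and 11.3% between 18 and 20 h. The test was limma's moderated F test of the cosine and sine terms, adjusted over all probes. A single day was sampled per series, so a rhythm here is a day-long course and not one seen to recur.

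**Figure D1:**
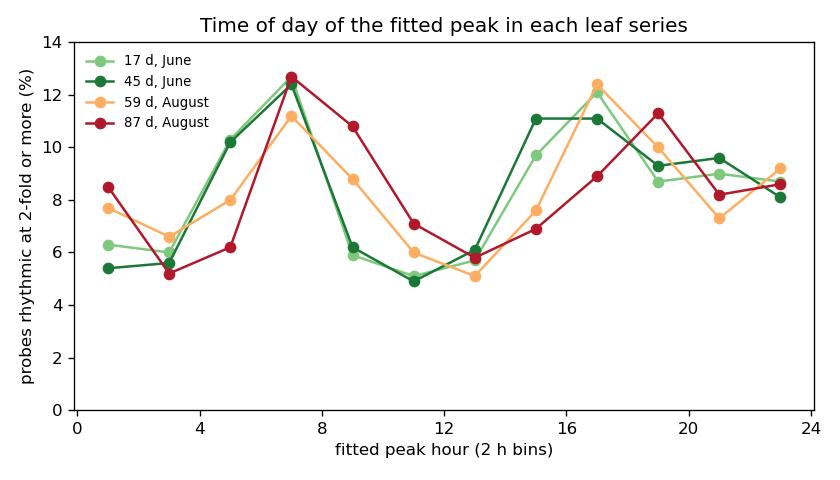
Percent of probes rhythmic at 2-fold or more (vertical axis) by fitted peak hour in 2 h bins (horizontal axis, clock hours), 1 line per leaf series. In all 4 series the share is higher in the bins around 7 h and in the late afternoon than around 11 h.

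The 4 probes with the largest swings in the main values peaked in the same part of the day in all 4 series. Probe eAry2_48790 (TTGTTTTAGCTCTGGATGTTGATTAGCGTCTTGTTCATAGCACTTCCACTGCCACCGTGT) had a mean peak-to-trough swing of 11.15 on the log2 scale over the 4 series. It peaked at 16.2 ± 0.31 h at 17 days (SE), 15.9 ± 0.27 h at 45 days, 16.8 ± 0.25 h at 59 days and 16.5 ± 0.25 h at 87 days, and its largest adjusted p in any series was 1.9e-12. Probe 44kb3_20036 (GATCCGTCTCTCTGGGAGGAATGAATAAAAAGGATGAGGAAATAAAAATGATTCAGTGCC) swung by 10.37 and peaked at 16.5, 15.9, 16.7 and 16.5 h in the same order of series. Other probes peaked in the morning with swings of similar size. Probe 44kb3_960 (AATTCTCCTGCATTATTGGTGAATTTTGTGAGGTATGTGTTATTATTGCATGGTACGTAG) had a mean swing of 10.76 over the 4 series. At 87 days its fitted swing was 10.63, and its samples ran from 5.96, which was not well above background, to 16.33. It peaked at 7.2 ± 0.23 h, 7 ± 0.25 h, 7.8 ± 0.22 h and 8.1 ± 0.24 h (adjusted p at most 1.5e-14). Probe 44kb3_11643 (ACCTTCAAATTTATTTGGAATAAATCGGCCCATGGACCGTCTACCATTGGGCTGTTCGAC) swung by 10.55 with peaks at 7.2, 7, 7.8 and 8.1 h. The morning probes followed each other closely over the samples, and so did eAry2_48790 and 44kb3_20036. Whether each pair reads the same transcript is not known here. Both morning probes were well above background in 10 of 13 samples at 59 and at 87 days, so their swings depend on the processing near the floor. On processed signals the swings were 12.99 for 44kb3_960 and 12.92 for 44kb3_11643, above the 11.78 of eAry2_48790 and the 10.97 of 44kb3_20036, so the order is not fixed.

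**Figure D2:**
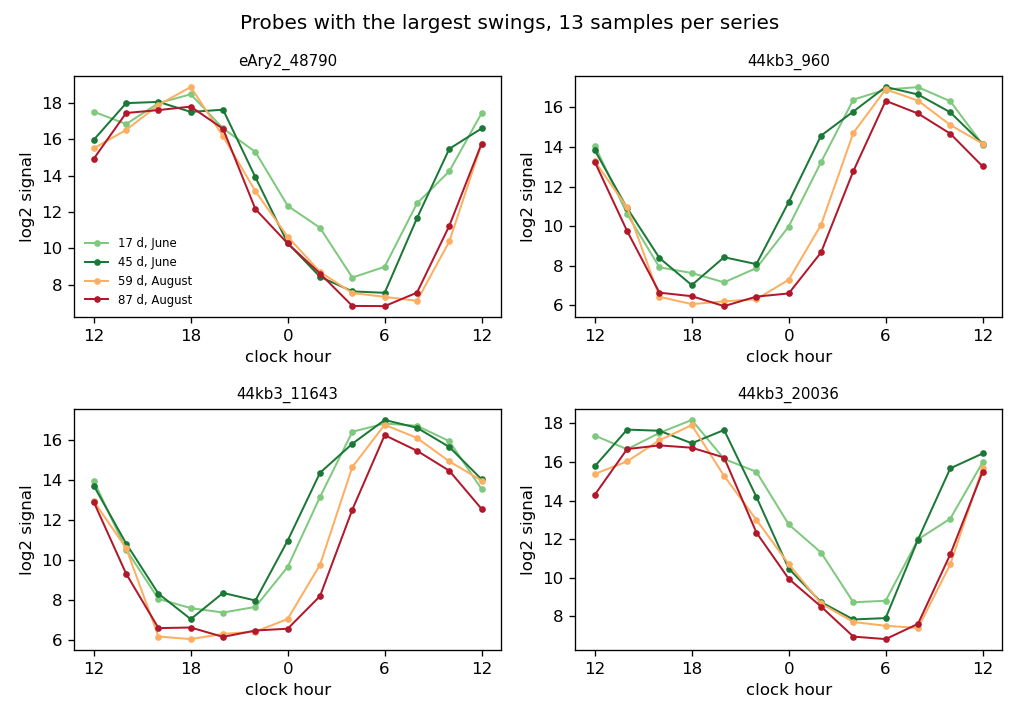
Log2 signal (vertical axis) against clock hour (horizontal axis) of the 4 probes with the largest mean swing, 1 point per sample and 1 line per series. A pair of probes peaks at 7 to 8.1 h and the other pair at 15.9 to 16.8 h in every series.

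Peak times lay later in August than in June in both plantings. Among the 18452 probes rhythmic with at least a 2-fold swing in all 4 series, the median peak was 0.95 h later at 87 than at 45 days, and 74.7% of these probes peaked later. Between 59 and 17 days the median was 0.51 h and 68.5% peaked later. Within a date the plantings lay closer together, with medians of -0.13 h for 45 against 17 days and 0.3 h for 87 against 59 days. The planting shift in June turned sign with slide as a fixed term (0.19 h) and without the second scan day (0.02 h). These medians describe probes chosen for a rhythm in every series and carry no test of their own. June and August samples were scanned on different days, so date and scan day cannot be told apart here.

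**Figure D3:**
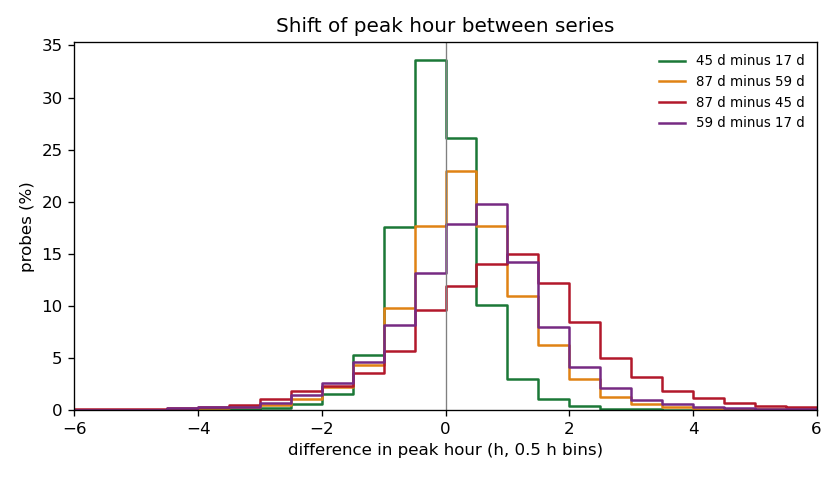
Percent of the 18452 probes (vertical axis) by difference in fitted peak hour between a pair of series (horizontal axis, h, bins of 0.5 h), 1 line per pair. The lines for August minus June are centred to the right of 0, with medians of 0.95 and 0.51 h.

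Which rhythms differed between the dates was tested probe by probe. Rhythms of 40987 probes (43.0%) differed between August and June, averaged over the plantings. Of the 11756 such probes with at least a 2-fold swing on both dates, 9202 peaked later in August, with a median shift of 1.25 h. The swing was at least 1.5 times smaller in August for 17958 called probes and at least 1.5 times larger for 9237. Probe 44kb3_37044 (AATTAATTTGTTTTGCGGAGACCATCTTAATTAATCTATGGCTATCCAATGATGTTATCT) swung by 1.87 in June with a peak at 2.3 h and by 0.25 in August, where 0 of 13 samples of either series were well above background (adjusted p 1.1e-12). Probe eAry2_48181 (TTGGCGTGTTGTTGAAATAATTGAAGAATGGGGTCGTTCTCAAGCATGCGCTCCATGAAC) went from 0.17 to 3.72 with an August peak at 23 h (adjusted p 1.7e-10), and 0 of its 13 samples were well above background in either June series. The rhythms of these probes differed between dates by 1.62 and 3.58, and on processed signals by 3.08 and 5.64. Probe 44kb3_6960 (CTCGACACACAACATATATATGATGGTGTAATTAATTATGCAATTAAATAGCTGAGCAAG) went from 1.17 to 3.13 (adjusted p 1.2e-11), with swings of 0.35 at 17, 2.02 at 45, 3.55 at 59 and 2.84 at 87 days, and was well above background in 0 of 13 samples at 17 days. With slide as a fixed term the count fell to 19891, and with 1 probe per sequence group, on 62920 probes, it was 25726.

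Plantings of the same date, which differ in age, were compared for differences in rhythm. In August, 5658 probes (5.9%) differed in rhythm between 87 and 59 days. Probe 44kb3_33138 (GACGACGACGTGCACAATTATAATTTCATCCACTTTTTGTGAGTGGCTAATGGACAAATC) swung by 1.3 ± 0.33 (SE) with a peak at 6.8 h at 59 days and by 4.03 ± 0.31 with a peak at 21.9 h at 87 days (adjusted p 9.4e-09). Probe 44kb3_5857 (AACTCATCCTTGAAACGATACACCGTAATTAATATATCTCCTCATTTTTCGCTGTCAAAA) swung by 0.07 ± 0.31 at 59 days and by 4.47 ± 0.29 at 87 days, where it peaked at 0.9 h (adjusted p 9.4e-09). In June, 80 probes differed between 45 and 17 days, and 9041 had an unadjusted p under 0.05. Probe eAry1_16182 (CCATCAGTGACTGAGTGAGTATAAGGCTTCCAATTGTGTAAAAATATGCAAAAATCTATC) swung by 4.25 ± 0.3 at 17 days and by 0.66 ± 0.3 at 45 days (adjusted p 4.3e-05). Probe eAry2_42906 (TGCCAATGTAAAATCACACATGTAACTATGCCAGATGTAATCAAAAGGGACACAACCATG) swung by 3.63 ± 0.26 and 0.71 ± 0.26 (adjusted p 7.4e-05). At 45 days both were well above background in 5 of 13 samples, so their small swings there were read mostly near the floor. A direct test found 1936 probes whose planting difference in rhythm was not the same in August as in June. It was run on the main values only.

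These planting counts depend on how the samples are grouped and blocked. With the samples of one date and time as a replicate block in place of the array, 18094 probes differed in June and 39733 in August, while slide as a fixed term gave 24 and 1291. Among 100 regroupings of time-matched samples, 16 gave as many probes in June and 7 in August, so chance is not excluded for either count. With 1 time point left out of every series in turn, the June count was 571 without time point 1 (the first noon), 38 without 2, 44 without 3, 52 without 4, 46 without 7, 49 without 8, 50 without 12 and 50 without the second noon, and the August count was 3711 without time point 6. The calls of eAry1_16182 and eAry2_42906 were lost on the scanner's processed signals and on the deposited value table, although the differences were of similar or larger size. For eAry1_16182 the rhythms differed by 3.6 in the main values, 3.45 on processed signals (adjusted p 0.16) and 3.67 on the deposited table (adjusted p 0.17). For eAry2_42906 they differed by 3.04, 3.74 (adjusted p 0.055) and 3.85 (adjusted p 0.063), and by 2.94 with slide as a fixed term (adjusted p 0.063). Why these calls ended was not tested.

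Time of day was then read from the transcriptome itself, with 200 rhythmic probes chosen in the 3 series other than the 1 being read. The estimate missed the clock by 0.33 h on average at 17 days, 0.62 h at 45 days, 0.45 h at 59 days and 0.54 h at 87 days. The June series ran ahead, by 0.32 ± 0.23 h at 17 days and 0.62 ± 0.41 h at 45 days (SD, n = 13), and the August series behind, by -0.4 ± 0.45 h at 59 days and -0.54 ± 0.47 h at 87 days. In August the lag was widest in the samples of 2, 4 and 6 h, with -0.87, -1.08 and -1.19 h at 59 days and -1.18, -1.35 and -1.16 h at 87 days. The June offsets were also lowest at 4 and 6 h, with -0.07 and -0.03 h at 17 days and 0.09 and 0.16 h at 45 days. The 45 day plants ran ahead of the 17 day plants by 0.31 ± 0.28 h, in 12 of 13 time-matched pairs (exact sign-flip permutation test over 8192 sign patterns, 2-sided p = 4.9e-04, adjusted over 2 comparisons 9.8e-04). Within the first scan day the lead was 0.37 ± 0.31 h in 8 of 9 pairs (exact sign-flip p = 0.0078). The pairs are successive samples of 1 day, and each series was read with its own 200 probes. They are therefore not independent replicates, and the sign-flip p-values do not measure the spread between plants or days. On simulated data with a delay of 1 h in a single series, that series read -1 h and the others 0.31 to 0.34 h, so a paired difference can exceed the true shift. The June series share a single slide, with 1 sample of 17 days, the first noon. It read 0.52 h ahead, and the 45 day sample of the second noon on that slide 0.23 h ahead. This pair, of noons a day apart, does not show the lead. The June peak shift given above turned sign with slide as a fixed term. The 87 day plants lay -0.14 ± 0.26 h from the 59 day plants, behind in 10 of 13 pairs (p = 0.076). That last comparison passed the threshold with 50 probes (-0.29 h, p = 0.0037), with all probes that met the conditions (-0.41 h, p = 7.3e-04) and on the processed signals (-0.22 h, p = 0.022). Offsets are relative to the other series, and all August samples share a scan day that no June sample has.

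**Figure D4:**
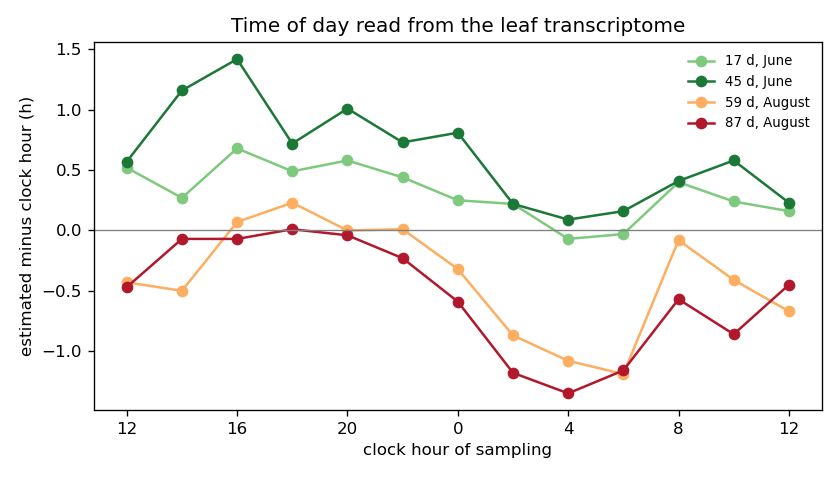
Estimated minus true clock hour (vertical axis, h) against clock hour of sampling (horizontal axis), 1 point per sample and 1 line per series. June samples lie mostly above 0, up to 1.42 h at 16 h, and August samples mostly below, down to -1.35 h at 4 h.

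The level of each transcript over the day was compared between the plantings on 1 date, a contrast named age here. The plantings differ in age and in when they were transplanted, with 1 series each. Age thus cannot be told apart from planting. In June, 8670 probes (9.1%) differed between 45 and 17 days, 4651 higher and 4019 lower in the older plants. Of these, 579 were at least 2-fold higher and 284 at least 2-fold lower, against 1900 and 742 on the scanner's processed signals and 1521 and 664 on the deposited value table. Probe 44kb3_23620 (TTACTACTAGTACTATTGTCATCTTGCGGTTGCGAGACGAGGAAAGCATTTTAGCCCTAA) had the largest rise, 5.89 on the log2 scale (SE 0.29, adjusted p 1.4e-17), from a mean of 6.57 ± 0.87 to 12.71 ± 0.86 (SD, n = 13), and was well above background in 2 of 13 samples at 17 days. Probe Cuffnpc_00332 (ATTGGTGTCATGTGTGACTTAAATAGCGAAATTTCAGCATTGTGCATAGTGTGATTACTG) rose by 5.45 (SE 0.23, adjusted p 2.9e-20). The 17 day series lies close to background for both, and the sizes moved with the processing, to 8.34 and 8.17 on processed signals. With slide as a fixed term they were 2.94 and 3.8. Their highest 17 day sample was the first noon (9.42 and 8.04), which shares its array with a 45 day sample. Both had higher means in August, 14.74 and 14.18 at 59 days. Probe eAry1_30472 (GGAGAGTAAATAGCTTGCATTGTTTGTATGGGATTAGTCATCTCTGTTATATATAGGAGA) changed by -4.12 (SE 0.52, adjusted p 4.6e-07), and 44kb3_25634 (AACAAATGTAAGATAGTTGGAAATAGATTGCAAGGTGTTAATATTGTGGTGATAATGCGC) by -3.3 (SE 0.42, adjusted p 7.0e-07). All 4 differences had the same sign in 13 of 13 time-matched pairs.

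The June count depends on the model. It was 17551 without the array block, 19124 with only the June series, 13754 with a 24 h cosine per series in place of time points and 1181 without the time-point term. It was 38 with slide as a fixed term, when the calls of eAry1_30472 (-3.37) and 44kb3_25634 (-2.46) were lost, 4170 with slide as a random block and 5123 without the second scan day, which holds 4 samples of 17 days only. The only slide with both June series holds 1 sample of 17 days, and there 72.0% of the 9036 probes called without that pair differed in the same direction. The share of called probes that were higher moved from 53.6% to 69.8% without the between-array step.

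In August, 30761 probes (32.3%) differed between 87 and 59 days, 15470 higher and 15291 lower at 87 days. At least 2-fold changes were seen in 2073 and 1663 of them, against 3902 and 3970 on processed signals and 3371 and 3414 on the deposited value table. Probe 44kb3_27298 (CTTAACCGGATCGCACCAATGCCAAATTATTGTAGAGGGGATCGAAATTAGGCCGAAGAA) rose by 5.05 (SE 0.38, adjusted p 2.9e-13), from 8.17 ± 0.93 to 13.19 ± 0.96 (SD, n = 13). Probe eAry2_21427 (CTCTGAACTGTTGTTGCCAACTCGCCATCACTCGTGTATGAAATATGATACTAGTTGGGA) rose by 4.8 (SE 0.23, adjusted p 1.1e-18) and had means of 6.97 and 7.26 in June. Probe eAry1_27418 (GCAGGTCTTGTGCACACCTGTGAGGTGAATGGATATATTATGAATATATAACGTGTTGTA) changed by -5.43 (SE 0.45, adjusted p 4.2e-12), from 12.53 ± 0.91 to 6.99 ± 1.28. Probe 44kb3_20070 (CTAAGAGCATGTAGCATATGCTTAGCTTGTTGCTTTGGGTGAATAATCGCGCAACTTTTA) changed by -5.23 (SE 0.44, adjusted p 7.1e-12). Both were well above background in 8 of 13 samples at 87 days, and on processed signals their changes were -7.55 and -7.18. All 4 had the same sign in 13 of 13 pairs. With slide as a fixed term 5655 probes differed, and on the only slide with both August series 91.0% of the 24354 probes called without its mixed pair differed in the same direction, with 1 sample per series.

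The age differences of the dates were then set against each other. Of the probes that differed by age on both dates, 841 were higher and 731 lower in the older plants on both, where independent calls would give 756 and 645. Another 2137 went in opposite directions, against 1400 if independent. Across all probes, which are not independent replicates, the age differences had a correlation of -0.1 (Spearman's rho -0.03). A direct test found that the age difference was not the same in August as in June for 23272 probes (24.4%), 11677 with a higher value in August and 11595 with a lower one. The share with a higher value was 50.2%, and 40.2% without the between-array step. Probe eAry1_30472, which was lower in the older plants in June, was higher in them in August (12.86 ± 0.81 at 87 days against 8.77 ± 0.87 at 59 days), a difference between dates of 8.3 (SE 0.72, adjusted p 2.4e-11). The difference was 8.14 for 44kb3_27298 (SE 0.52, adjusted p 1.4e-14). Probe eAry1_41883 (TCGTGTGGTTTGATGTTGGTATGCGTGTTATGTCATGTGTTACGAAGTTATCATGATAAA) went the other way, with means of 8.43, 11.76, 12.16 and 7.59 from 17 to 87 days and a difference of -8.14 (SE 0.68, adjusted p 9.2e-12). Probe eAry2_40456 (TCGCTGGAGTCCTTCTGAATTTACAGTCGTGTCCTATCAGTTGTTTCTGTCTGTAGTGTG) had -8.2 (SE 1.07, adjusted p 2.3e-07), and -11.46 on processed signals, with 4 of 13 samples well above background at 17 days. With slide as a fixed term 6891 probes passed and the call of eAry2_40456 was lost (-5.66). Slide as a random block gave 14641.

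**Figure D5:**
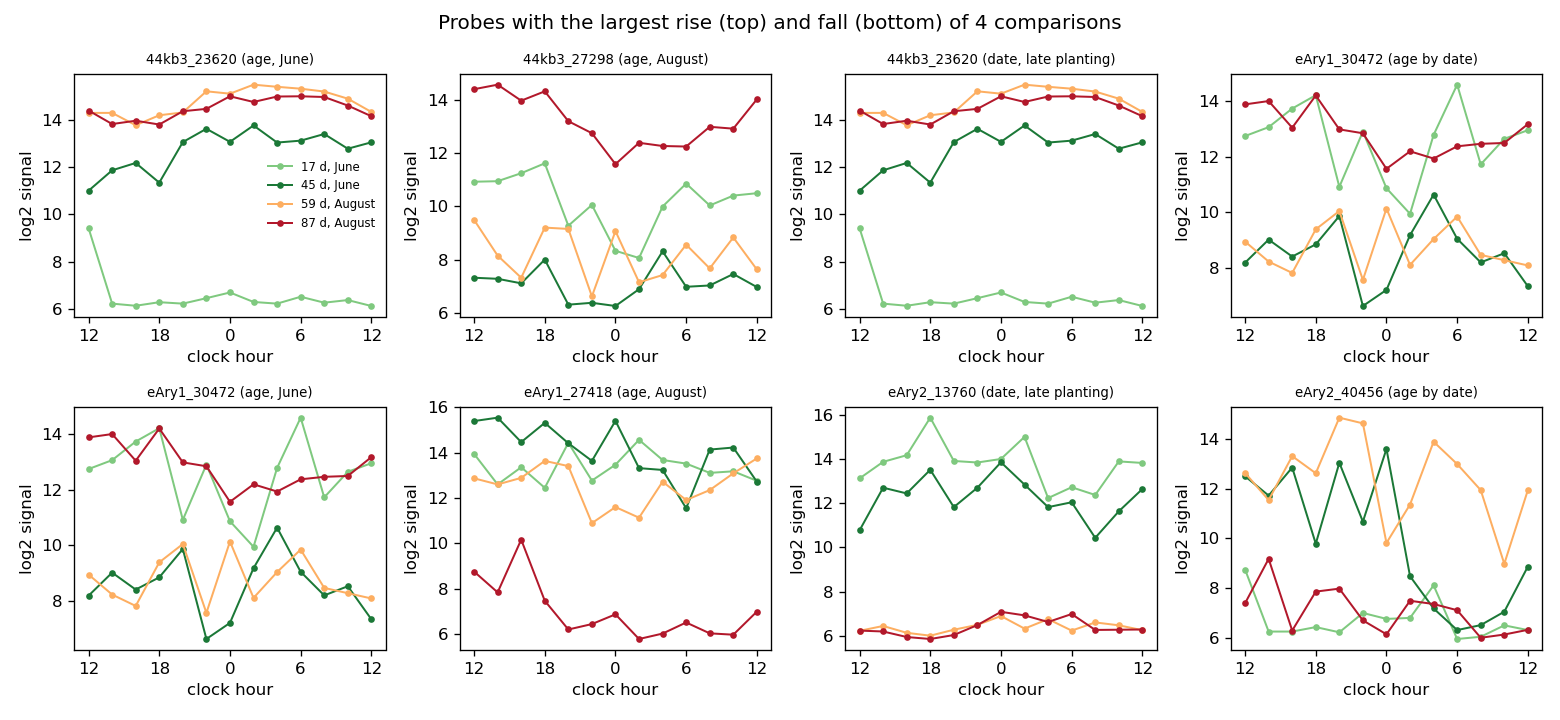
Log2 signal (vertical axis) against clock hour (horizontal axis) of the probe with the largest rise (top) and the largest fall (bottom) in each of 4 comparisons, 1 point per sample and 1 line per series. Probe 44kb3_23620 was higher at 45 than at 17 days in 13 of 13 time-matched pairs (means 12.71 and 6.57).

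Each planting was followed from June to August, when its plants were older and the season later. In the early planting, 64508 probes (67.7%) differed between 87 and 45 days, 31277 higher and 33231 lower in August. In the late planting, 54402 probes (57.1%) differed between 59 and 17 days, 25254 higher and 29148 lower. At least 2-fold, 7411 rose and 7794 fell in the early planting, and 5535 rose and 4597 fell in the late one. On processed signals these counts were 11942 and 13365 in the early and 9969 and 8841 in the late planting, and in the values deposited by the authors they were 9830 and 11506, and 8054 and 7583. Most changes shared by the plantings had the same direction, with 19977 probes higher in August in both (8295 if independent), 22557 lower in both (10173) and 1708 opposite (18388). Across probes, the correlation of the plantings' date differences was 0.77 (Spearman's rho 0.77).

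In the early planting PPNTpc_00175 (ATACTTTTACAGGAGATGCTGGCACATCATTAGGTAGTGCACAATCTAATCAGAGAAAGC) rose most, by 7.77 (SE 0.27, adjusted p 3.5e-24), from 8.42 ± 0.8 to 16.12 ± 0.49 (SD, n = 13), followed by eAry1_14244 (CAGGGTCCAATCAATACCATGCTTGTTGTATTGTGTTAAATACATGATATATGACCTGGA) with 6.92 (SE 0.2, adjusted p 3.4e-26). The largest falls were those of eAry1_27418 (-7.01, SE 0.46, adjusted p 4.5e-16) and 44kb3_20070 (-6.51, SE 0.45, adjusted p 2.3e-15), the pair that also fell with age in August, a contrast that shares the 87 day series, and on processed signals their changes were -9.18 and -8.55. In the late planting 44kb3_23620 rose by 8 (SE 0.3, adjusted p 1.4e-22) and Cuffnpc_00332 by 7.71 (SE 0.23, adjusted p 1.6e-25), the pair that also rose with age in June, a contrast that shares the 17 day series. Probe eAry2_13760 (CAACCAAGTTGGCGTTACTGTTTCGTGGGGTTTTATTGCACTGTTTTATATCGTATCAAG) changed by -7.31 (SE 0.33, adjusted p 3.2e-20), from 13.76 ± 1 at 17 days and 12.25 ± 0.97 at 45 days to 6.39 in both August series, where it was well above background in 3 and 4 of 13 samples. Probe eAry1_40004 (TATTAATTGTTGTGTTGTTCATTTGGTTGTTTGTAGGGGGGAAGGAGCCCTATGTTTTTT) changed by -7.16 (SE 0.33, adjusted p 6.1e-20) and was well above background in 2 and 4 of 13 August samples. On processed signals the last 4 changes were 10.49, 10.44, -10.05 and -10.19, each against a group near background. All 8 differences had the same sign in 13 of 13 pairs. No June and August samples share a slide or a scan day, so the date comparisons have no within-batch value. The August minus June differences of 10 spike-in probes had an SD of 0.1, against 0.78 for 46490 leaf probes of the same brightness. These spike-in differences had a median of -0.35 and ran from -0.52 to -0.16, against a leaf median of -0.01. They were taken without the between-array quantile step, so the SDs are not strictly comparable. Without the between-array step the share of called probes that were higher in August moved from 48.5% to 58.1% in the early planting, with 9544 rising and 6418 falling at least 2-fold. In the late planting it moved from 46.4% to 64.0%, with 7984 and 3048, and the median of all probes from -0.02 to 0.14. Which direction was the more frequent thus depends on that step.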

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

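The spike-in test, the test of August against June planting differences in rhythm and the runs without single time points were chosen after the results were seen, and the other tests in this part before.

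Each of the following results stands out as a difference between groups found by a direct test of that difference. The age difference in level was not the same on both dates for 23272 probes (1 of 100 splits as large, highest other 3). Each planting on a date is 1 series, so these splits do not exclude chance between series. Slide terms lowered this count, as given above. The rhythm differed between dates for 40987 probes (1 of 100, highest other 29211). It differed between plantings for 80 probes in June (16 of 100, highest other 2847) and for 5658 in August (7 of 100, highest other 17267), and chance is not excluded for either count. The planting difference in rhythm was not the same in August as in June for 1936 probes (1 of 100, highest other 1636). Only the real split was as large, but another came close, so chance is not firmly excluded for this count. It was not run with slide terms, other blocks or time points left out. Every regrouping exchanged series only between samples of the same clock hour, so it parted as many time-matched pairs as the real split. The splits that called several times the real count by planting point to a structure of the samples. Exchanging some hours and not others turns differences in level between the series into a course over the day. Splits by date do the same, so they cannot exclude chance for the 40987 probes.

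June and August differed in level at 67.7% of probes in the early and 57.1% in the late planting. Scan batches as the whole cause are argued against by 10 spike-in probes, within a limit. Their differences between dates had an SD of 0.1, 0.126 times the 0.78 of 46490 leaf probes of the same brightness. The spike-in values are means of 60 spots, centred by array without the between-array quantile step, so the SDs are not strictly comparable. All 10 spike-in probes lay lower in August, with a median of -0.35 (-0.52 to -0.16), against a leaf median of -0.01. The SDs do not measure this common offset. The change of scan day inside the 17 day series, which falls on its last 4 samples, called 7195 probes, between the bounds set beforehand for and against this cause. Dim probes lifted by brighter August scans are argued against by the 59.3% called in the late planting among probes well above background in all 52 samples. Differences in sample handling before the spike-ins were added may still contribute, and season and plant age stay open as untested.

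Peak times lay later in August, by a median of 0.95 h between 87 and 45 days. A waveform that a single cosine does not describe is argued against by a shift of 0.8 h with 24 h and 12 h terms, and the normalization by a shift of 0.89 h on the deposited value table. With slide as a fixed term the shift was 0.63 h, and 0.67 h between 59 and 17 days (0.51 h without that term). Slides hold neighbouring time points of a series, so a part of the shift could be theirs and cannot be told apart from them. The date, with its later sunrise, and plant age are the biological explanations of the design and were not tested.

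With the array as block the plantings differed in rhythm at 5658 probes in August and 80 in June, but with the time-matched samples of a date as a replicate block at 39733 and 18094, so the June count depends on the model. A single August time point is argued against by a lowest count of 3711, without time point 6, and a wider spread in June by a ratio of the residual SDs of 1.05. With slide as a fixed term the August count was 1291, so neighbouring time points on shared slides could make up much of it, and both cannot be told apart. The splits above leave chance open for each date. The direct comparison of the dates called 1936 probes, a count that was not run with slide as a fixed term. The ages of the plantings (59 and 87 days against 17 and 45) were not tested as an explanation.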

How the results depend on the processing

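The runs without the second scan day or single time points, with 1 probe per sequence group and with scan day as a fixed term were chosen after the data were seen. Of the alternatives chosen before that, 124 left the count or value of a comparison within its limits. Another 31 moved it and 3 took it past the threshold. For a count the limit was a factor of 1.5. Of the alternatives added later, 155 left the count or value within its limits and 23 moved it. Runs without single time points, 12 for each count, make up most of the added ones. Of those runs, only 7 for the June and 1 for the August rhythm difference by age moved. The other added runs thus moved more often. Of the values of single probes and median shifts, 432 under the alternatives chosen before and 103 under those added counted as the same. For a probe this meant the same sign and the same side of the threshold, whatever the size. For a median shift it meant the same sign and a change within the SD across probes. Another 10 fell below the threshold and 2 reversed. Signal over background limits what can be seen, since 95217 of 151878 probes passed the filter.

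With 1 probe per sequence group the tests covered 62920 probes, and this smaller number lowered the counts to 46313, 43428, 42514 and 38575 for rhythms at 17, 45, 59 and 87 days, 5582 and 20016 for age in June and August, 42182 and 35513 for date in the early and late planting, 15149 for age by date, and 25726, 49 and 3528 for rhythm differences by date and by age in June and August. For the values that follow, the cause was not tested. Age in June was 4790 without the between-array step, 17551 without the array block, 4170 with slide as a random block, 38 with slide as a fixed term, 1181 without the time-point term that pairs the samples, 13754 with a cosine in place of time points, 19124 with only the groups compared, 5123 without the second scan day and 5115 with scan day as a fixed term. Age in August was 5655 with slide as a fixed term and 13087 without the time-point term. Date in the late planting was 28604 without the time-point term. Age by date was 14641 with slide as a random block, 6891 as a fixed term and 6888 without the time-point term. The rhythm difference by date was 19891 with slide as a fixed term.

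The June rhythm difference by age was 18 on processed signals, 11 without the between-array step, 10 on the deposited value table (82019 probes), 133 without the filter, 6 with probes bright in all samples, 1985 without the array block, 180 with slide as a random block, 24 as a fixed term, 50 without the second noon, 885 with 24 h and 12 h terms, 18094 with the replicate block, 136 without the second scan day, and 38 to 571 without single time points. The August one was 3331 with probes bright in all samples, 13331 without the array block, 10077 with slide as a random block, 1291 as a fixed term, 10778 with 24 h and 12 h terms, 39733 with the replicate block, and 3711 to 6441 without single time points. The estimated time of 87 against 59 days passed the threshold with 50 probes (-0.29 h), all probes (-0.41 h) and processed signals (-0.22 h). The median peak shift of 45 against 17 days (-0.13 h) turned to 0.19 h with slide as a fixed term and to 0.02 h without the second scan day.

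Not run were the means over all probes of a gene and the gene lists, which need a gene for each probe. The direct test of August against June planting differences in rhythm was not run under the alternatives either. The date contrasts could not be fitted with slide or scan day as a fixed term.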

Other observations

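The tests on the August lag and on the noon samples were chosen after the results were seen, and the tests on opposite strands and the splits before.

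Between neighbouring samples, the SD of the log2 change across probes was largest in the morning, with 0.55 from 8 to 10 h at 17 days, 0.49 from 8 to 10 h at 45 days, 0.54 from 6 to 8 h at 59 days and 0.59 from 4 to 6 h at 87 days. The step at 17 days lies between arrays and the others within an array, and samples of one array are correlated, so their sizes are not strictly comparable. Noon differed from midnight by an SD of 0.94, 0.88, 0.9 and 0.91 in the order of age. The noons of one series, a day apart, differed by 0.42, 0.48, 0.34 and 0.45. The first 3 principal components of the 52 samples held 35.3%, 22.2% and 20.2% of the variance.

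The share of rhythmic probes was also taken by the prefix of the probe name, without a test between the classes. For names beginning eAryKoshi (3435 probes in 1602 sequence groups) it was 75.7%, 56.2%, 68.9% and 62.9% at 17, 45, 59 and 87 days. For those beginning PPNTnpc it was 67.6%, 54.9%, 61.2% and 54.3%, and for the 28237 probes beginning 44kb3 it was 75.8%, 72.1%, 70.9% and 65.0%. What the prefixes stand for is not given in the sources used here.

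Transcripts on opposite strands of one sequence might share their time of day. Of 305 pairs of opposite-strand groups, 52 had both members rhythmic in all 4 series, and their peak differences had a resultant length of 0.161, below the 0.239 that marks the 95th percentile of 10000 random pairings (permutation test, 1-sided p = 0.3). The median correlation over the 52 samples was 0.16 over all pairs, which argues against one double-stranded signal read by both probes. In 26 pairs the correlation was at least 0.8, and in 47 it was under -0.5.

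The estimated time lagged most from 2 to 6 h in August, and the June offsets were also lowest at 4 and 6 h. Later peaks of the probes that peak near dawn alone might account for the August lag. Probes that peak from 4 to 8 h shifted 0.1 h more between 45 and 87 days than those that peak from 14 to 20 h. Between 17 and 59 days they shifted 0.03 h more. The median shift of the 4 to 8 h probes was 1.13 and 0.62 h. For peaks from 8 to 14 h it was 0.54 and 0.3 h. For peaks from 20 to 4 h it was 1 and 0.42 h. Later peaks were thus not confined to probes that peak near dawn, although those shifted most. The medians cover probes rhythmic in all series, not those that gave the estimated time, so they cannot decide this explanation.

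The first noon samples of the younger series share an array with an older series. Of 10 probes with a median under 7.5 at 17 days and at least 3 higher at 45 days, the first noon was the highest sample of the 17 day series in 8, with a median excess of 1.35. At 59 against 87 days it was the highest in 5 of 42 such probes, with a median excess of -0.07. The limits were chosen after the values were seen, and other limits gave 8 of 9 and 5 of 29 probes (median under 7), and 4 of 5 and 3 of 8 (at least 4 higher). The cause was not tested.

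For the results not discussed above, splits of the samples gave the following. Rhythms at 17, 45, 59 and 87 days called 71331, 66695, 66038 and 60238 probes, and the highest count under a random order of the times was 30397, 34681, 29998 and 36160. Age called 8670 probes in June (highest other 470) and 30761 in August (8881). Date called 64508 in the early planting (29127) and 54402 in the late planting (34914). In each of these, 1 of 100 splits, the real one, was as large. A random order of the times breaks any smooth course, including one from slides that hold neighbouring time points. The level splits exchanged successive samples of 1 series per planting and date. Random labels on the samples are thus argued against. Chance between days or series is not excluded, nor are batches that run with the series or the time points.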
